A study of Mus musculus with 9 samples.

How the data were processed

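Liver RNA was sequenced from male C57BL/6J mice of 3 genotypes, all given diethylnitrosamine (DEN), a liver carcinogen, by intraperitoneal injection and kept on chow. The dose was 25 mg per kg at 14 days of age and livers were collected at 6 months, per the labels. Total RNA was extracted with Trizol, treated with DNase, selected with oligo(dT) and made into cDNA libraries, per the labels' protocols. Each library is a pool of RNA from 3 mice of 1 genotype, and 3 pools per genotype give 9 libraries from 27 mice. The spread between pools is smaller than that between single mice would be, and the values of single mice were not measured.

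Counts of reads per gene were deposited as whole numbers, not normalized, with 41388 genes in each table, per the file headers. The same tables hold CPM and RPKM values computed by the authors; these were recomputed from the counts and gene lengths, and the largest differences were 5.1e-11 CPM and 4.7e-11 RPKM. The deposited CPM and RPKM columns were not used in any test. STAR 2.0.4b, Subread and featureCounts 1.4.5 are named in the submitters' processing notes, with no role stated. The genome build, the annotation, the handling of reads that match several genes and the strand setting are not given in the sources used here. Of the Ensembl identifiers, 97.47% matched GENCODE M21 (GRCm38), 82.17% of the matched genes had the same start, and 99.75% of those on chromosomes lay within 100 kb of it. Coordinates are printed as the deposited tables give them. Where near-identical genes exist, as in the Mup family, the C1r and C1s pairs, the carboxylesterases and ribosomal protein genes, reads may be split between copies and single-gene values are uncertain. Antisense and overlapping genes are uncertain too.

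Total counts ran from 24995426 to 27080442 in the control libraries, from 26362408 to 27918197 in MttpLKO and from 23268389 to 23429588 in DKO. A search for repeat deposits of 1 library found no pair of replicates that agreed within sampling noise (chi-square per degree of freedom of 21.4 to 71.3). That the libraries are separate pools rests on the labels. Genes were kept by filterByExpr in edgeR 4.0.16 (R 4.3.3) with a minimum count of 10, which left 14741. Libraries were scaled by TMM. The common dispersion was 0.0335, a biological coefficient of variation of 18.3%.

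Differences between genotypes were tested with edgeR's quasi-likelihood F test on the counts, in 1 fit of 3 genotype means over all 9 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values printed with SD are on TMM-scaled library sizes. Gene lists, 36 in number, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison; 35 had at least 3 tested members. Camera with an estimated correlation and fry were the alternatives. Beside each list test stand the members called with adjustment over all genes and those called when adjusted over the list alone.

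The design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Mttp and Fabp1; the 8 largest rises and the 8 largest falls per comparison among named genes with adjusted p under 0.05, a mean CPM of at least 5 in 1 of the 2 genotypes and no overlap between the 3 libraries of one and the 3 of the other; up to 3 called members of each of the 8 lists with the smallest camera p; and the 2 members with the smallest adjusted p of 8 fixed lists. Chance gives no overlap between 3 and 3 libraries in 10% of genes. Any gene named outside the rule is said to be chosen after its values were seen.

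The tests were run first on simulated counts for these genes with 200 changed by known folds. For MttpLKO vs control edgeR recovered 64.9% of genes changed 2-fold and 91.7% of those changed 4-fold, with 6 false of 157 calls. For DKO vs MttpLKO it recovered 58.6% and 87.9%, with 10 false of 155 calls, and for DKO vs control 56% and 89.8%, with 7 false of 151. DESeq2 on the same counts made 23 false of 175, 34 of 187 and 40 of 197 calls. These counts were drawn for each gene on its own at edgeR's dispersions, with no correlation between genes and no outlying pool. Error rates in the real data may be higher, and the setting may favour edgeR. Shared changes and genes that moved back were set against 40 simulations of the 9 libraries with the fitted spread of each gene, with either all genotypes unchanged, or DKO set equal to MttpLKO and the MttpLKO changes kept for called genes. Alternatives covered other scaling (RLE size factors, upper quartile), other low-count filters, DESeq2 1.42.0, limma-voom, removal of the 20 most abundant genes, a minimum absolute log2 fold change of 1, the 6 compared libraries alone, and leaving out each library in turn. DESeq2 as planned tested the 25483 genes with a count, with its own filtering, and its counts of list members come from that run. A robust fit, limma-voom with library weights and DESeq2 on the 14741 genes that edgeR tested were added after seeing the data. No sample was left out.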

Results

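The series measured polyadenylated liver RNA in DEN-treated male mice of 3 genotypes: floxed Mttp (control), Mttp deleted in the liver alone (MttpLKO), and that deletion plus germline loss of Fabp1 (DKO). Mttp encodes the microsomal triglyceride transfer protein that loads lipid onto apolipoprotein B for secretion as VLDL, and Fabp1 encodes the abundant liver fatty acid-binding protein. The question, from the series title, concerns liver tumours when VLDL secretion is impaired, and whether Fabp1 loss adds to it. There were 3 pooled libraries per genotype, each a pool of RNA from 3 mice, with 23268389 to 27918197 counts. The DKO libraries, at 23268389 to 23429588 counts, were shallower than all others. The labels name liver and do not say whether the pools held tumour or non-tumour tissue, so tumour marker, cell cycle and matrix values may reflect either. No tumour counts, histology or lipid measurements were used here, and no Fabp1 single knockout was among the samples.

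Both deletions were visible in every library of the genotypes concerned. Mttp read 3.24 to 9.78 CPM in each of the 6 MttpLKO and DKO libraries and at least 69.4 in each control, and Fabp1 read 50.3 to 78.0 CPM in each DKO library and at least 3379 in the others. Mttp (chromosome 3, 138089855 to 138143388) stood at 110 ± 61.5 CPM in control (SD, n = 3), 7.39 ± 2.07 in MttpLKO and 4.52 ± 1.28 in DKO. Control replicate 1 held 180.8 CPM of Mttp, above the 79.9 and 69.4 of the other control pools. Mttp was 14.9-fold lower in MttpLKO than in control (log2 fold change -3.89 ± 0.38 SE, edgeR adjusted p = 0.000906) and 24.3-fold lower in DKO than in control (edgeR adjusted p = 0.000396). Fabp1 (chromosome 6, 71199827 to 71205023) stood at 6381 ± 412 CPM in control, 4120 ± 810 in MttpLKO and 65.2 ± 14.0 in DKO. It was 63.1-fold lower in DKO than in MttpLKO (log2 fold change -5.98 ± 0.23 SE, edgeR adjusted p = 1.19e-07), and its difference between MttpLKO and control did not pass the test (log2 fold change -0.63 ± 0.18 SE, edgeR adjusted p = 0.35). Gene totals do not show which exons were lost.

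**Figure D1:**
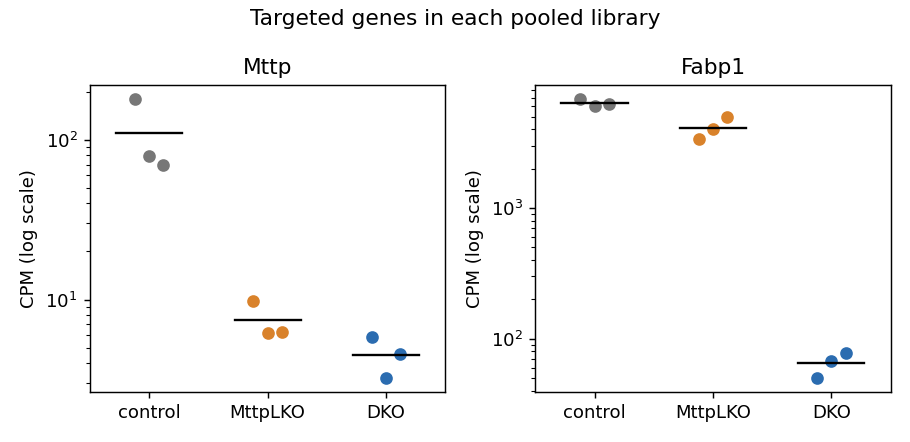
CPM of Mttp and Fabp1 on a log axis for each of the 9 libraries, with 1 point per pool and a line at the genotype mean. Mttp averages 110 CPM in control and 7.39 in MttpLKO, and Fabp1 averages 65.2 CPM in DKO.

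MttpLKO was compared with control to see how DEN-treated livers without Mttp differ. MttpLKO livers had higher Akr1c18, Asns and Ces1b, lower major urinary protein genes Mup7 and Mup9, and high counts of the complement protease genes C1s2 and C1rb, which were near 0 in control. Ces1b, a carboxylesterase gene, rose 3.85-fold from 91.5 ± 7.03 to 353 ± 14.8 CPM (edgeR adjusted p = 0.00421). Asns, which encodes asparagine synthetase, rose 4.97-fold (edgeR adjusted p = 0.0372), and Akr1c18, a hydroxysteroid dehydrogenase gene, rose 12.5-fold to 13.8 ± 13.6 CPM (edgeR adjusted p = 0.0479). C1s2 went from 0.125 ± 0.094 to 38.8 ± 1.32 CPM and C1rb from 0.136 ± 0.089 to 31.5 ± 1.61 CPM (edgeR adjusted p = 6.5e-08 and 1.04e-06). Gprc5a and Pianp rose as well, by 51.3-fold and 11.9-fold, and Gh, the growth hormone gene, rose from 0.065 ± 0.061 to 12.2 ± 6.03 CPM (edgeR adjusted p = 0.000312), while the pituitary hormone genes Prl, Cga, Tshb, Lhb and Fshb, chosen after values were seen, had 0 counts in the MttpLKO and DKO libraries and Pomc had 26, against 16 in control.

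Among the falls, Mug2, a murinoglobulin gene, dropped 6.99-fold from 211 ± 18.7 to 30.2 ± 12.2 CPM (edgeR adjusted p = 0.000409). Rpl34, a ribosomal protein gene with near-identical copies elsewhere, fell 10.5-fold (edgeR adjusted p = 2.4e-06). It starts at 130726831 on chromosome 3, the chromosome of Mttp. Mup9 and Mup7 fell 6.34-fold and 2.66-fold (edgeR adjusted p = 0.042 for each), and Clec2h, Obp2a, Crygn and Bmyc fell 109-fold, 13.8-fold, 6.14-fold and 2.98-fold. Over all genes, 33 rose and 18 fell among 14741 tested by edgeR's quasi-likelihood test, and 1028 had an unadjusted p under 0.05 where 737 are expected by chance. Of the 51 called genes, 15 lay between 119353150 and 139969284 on chromosome 6, among them C1s2, C1rb, Mug2, Pianp, Clec2h and Gprc5a. Another 6 lay between 80980734 and 85082339 on chromosome 8.

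Few secretory and storage lipid genes passed the test. Of 30 VLDL assembly and lipoprotein genes, edgeR called Mttp alone, with adjustment over all genes and when adjusted over the list alone, and DESeq2 called 1 lower. Apoa4, which encodes a triglyceride-rich lipoprotein component, was at 57.8 ± 6.28 CPM against 87.6 ± 6.66 in control (edgeR adjusted p = 0.306). Of 25 lipid droplet genes edgeR called none over all genes and 1 lower when adjusted over the list alone. At an unadjusted p under 0.05 there were 3, and DESeq2 called 1 lower. Cidec, a lipid droplet protein gene, was 2.42-fold lower (edgeR adjusted p = 0.113) and Mgll, a monoglyceride lipase gene, 1.35-fold lower (edgeR adjusted p = 0.362). Of 25 fatty acid and triglyceride synthesis genes none was called by edgeR with either adjustment or by DESeq2, and 3 had an unadjusted p under 0.05. Scd1 was at 940 ± 469 against 1772 ± 383 CPM and Fasn was at 333 ± 80.0 against 568 ± 73.3 CPM. As groups these 3 lists were called lower by camera, at adjusted p = 0.0431, 0.0234 and 0.0234, and each had an adjusted p = 0.501 with an estimated correlation. The VLDL list holds Mttp, deleted by design, and its median log2 fold change was -0.032 against a mean of -0.164. Camera was not run without Mttp, so that call does not show a fall of the other members. The 10 adipocyte genes, Cidec and Cidea among them, were lower for 7 (camera adjusted p = 0.0431; adjusted p = 0.501 with an estimated correlation). Of these edgeR called none over all genes and 1 higher and 2 lower when adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 1 lower. Their median of -0.21 was -0.14, -0.36, -0.13 and -0.12 without control replicate 2 and MttpLKO replicates 1, 2 and 3, and the call was lost each time (camera adjusted p = 0.239, 0.0547, 0.181 and 0.148). The 38 fatty acid oxidation and PPARalpha targets were higher by camera (adjusted p = 0.0221; adjusted p = 0.631 with an estimated correlation), with none called by edgeR over all genes, 2 higher when adjusted over the list alone, 3 at an unadjusted p under 0.05 and 2 higher by DESeq2. Acot3 and Acot4, acyl-CoA thioesterase genes, were 2.76-fold and 1.74-fold higher (edgeR adjusted p = 0.135 and 0.14). Without MttpLKO replicate 2 the VLDL, synthesis and oxidation lists lost the call (camera adjusted p = 0.0805, 0.303 and 0.695), as did the synthesis and oxidation lists without control replicate 1 (0.244 and 0.553), the droplet list without control replicates 2 and 3 (0.0808 and 0.0682), the droplet and oxidation lists without MttpLKO replicate 1 (0.054 and 0.112) and the VLDL and droplet lists without MttpLKO replicate 3 (0.162 and 0.183). Of 19 fatty acid uptake and binding genes none was called by edgeR with either adjustment or by DESeq2, 3 had an unadjusted p under 0.05, and Fabp2, an intestinal-type binding protein gene, was 1.8-fold lower (edgeR adjusted p = 0.338). That list was not called by camera (adjusted p = 0.377), with a median of 0.02 and a mean of -0.096 in log2 units and a test pointing down.

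Liver genes with a sex bias had the smallest camera p of the lists, at the preset correlation. Male-biased genes were lower in MttpLKO for 24 of 27 members, with Mup7 called over all genes and 9 lower when adjusted over the list alone (camera adjusted p = 6.19e-14; adjusted p = 0.19 with an estimated correlation). Female-biased genes were higher for 15 of 19, with Abcd2, a peroxisomal fatty acid transporter gene, called at 2.86-fold (edgeR adjusted p = 0.0356) and 6 higher when adjusted over the list alone (camera adjusted p = 7.01e-11; adjusted p = 0.19 with an estimated correlation). Control replicate 1 lay apart on both lists, with scores of 0.336 and -0.652 against -0.208 to -0.128 and 0.3 to 0.352 in the other controls. Without it the medians of -0.51 and 0.63 were -0.35 and 0.53 (camera adjusted p = 8.04e-08 and 4.49e-07), and without control replicate 3 the female-biased median was 1.10. Interferon response genes were lower for 36 of 38 with none called by edgeR with either adjustment or by DESeq2 and 6 at an unadjusted p under 0.05 (camera adjusted p = 8.45e-07; adjusted p = 0.501 with an estimated correlation), and their median of -0.23 was -0.15 without MttpLKO replicate 2.

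Liver tumour and fetal liver markers were higher for 36 of 43 members (camera adjusted p = 5.51e-10; adjusted p = 0.294 with an estimated correlation). By edgeR Akr1c18 was the 1 gene called over all genes, and 13 were higher and 2 lower when adjusted over the list alone; DESeq2 called 8 higher and 1 lower. The list score was 0.993 in MttpLKO replicate 3 and 0.318 and 0.524 in replicates 1 and 2. Meg3, an imprinted noncoding RNA gene, stood at 13.5 ± 3.28 CPM against 6.56 ± 1.13 (edgeR adjusted p = 0.0889). ER stress genes were higher for 22 of 30 with Asns called by both adjustments (camera adjusted p = 8.35e-05; adjusted p = 0.501 with an estimated correlation). The male-biased, female-biased, tumour marker, ER stress and interferon lists stayed past the preset-correlation threshold without each library in turn. In all, camera called 13 lists higher and 9 lower at the preset correlation and none with an estimated correlation. Among the 13 higher were NRF2 and oxidative stress (28 of 35), acute phase (22 of 32) and immediate early genes (15 of 22). Their camera adjusted p was 0.00325, 0.0288 and 0.0234 (0.501, 0.609 and 0.501 with an estimated correlation). EdgeR called none of their members over all genes.

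A set of lists rested on MttpLKO replicate 3. This library lay apart on the first principal component, at 53.7 against -17.4 to 9.62 for the other libraries, and held 9.34 CPM of Mki67, a proliferation gene chosen after its values were seen, where the other MttpLKO pools held 0.726 and 1.03. Its cell cycle score was 1.12 log2 units above the control mean against 0.019 and -0.082 in the other MttpLKO pools, its matrix score 0.836 against 0.024 and 0.19, and its B and plasma cell score 3.22 against -0.035 and 0.247. Cell cycle genes (37 of 41 higher, camera adjusted p = 8.35e-05) and extracellular matrix genes (38 of 44 higher, camera adjusted p = 5.1e-07) had none called by edgeR with either adjustment, 2 and 14 at an unadjusted p under 0.05, and 0 and 1 called higher by DESeq2. B and plasma cell genes (16 of 16 higher, camera adjusted p = 3.38e-05) had none called by edgeR over all genes, 7 when adjusted over the list alone, 8 at an unadjusted p under 0.05 and 1 by DESeq2 (2 on the genes edgeR tested), and all 3 lists had an adjusted p = 0.501 with an estimated correlation. Without replicate 3 the camera adjusted p was 0.844, 0.162 and 0.687; the cell cycle median turned from 0.52 to -0.004, and the B and plasma cell median from 1.73 to -0.017. Stellate cell, bile duct and recruited macrophage lists also lost the call without it (camera adjusted p = 0.724, 0.162 and 0.799). In the same comparison Tk1 and Cdkn3 (cell cycle) were 1.43-fold and 3.25-fold higher and Mgp and Spp1 (matrix) 3.1-fold and 1.66-fold higher, none past the test (edgeR adjusted p = 0.521, 0.578, 0.154 and 0.338).

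The count of 51 called genes was 14 without control replicate 2 or 3, 25 without control replicate 1, 19 without MttpLKO replicate 2 and 29 without DKO replicate 2. It was 166 with DESeq2 on all genes with a count and 165 with DESeq2 on the genes edgeR tested. Of the 18 named genes called, 8 (Mttp, C1s2, C1rb, Gh, Ces1b, Rpl34, Mug2 and Crygn) were called under each alternative. The other 10 lost the call in at least 1. The largest leave-one-out edgeR adjusted p was 0.239 for Akr1c18 without control replicate 2, 0.176 for Asns and 0.13 for Abcd2 without control replicate 3, 0.166 for Clec2h and Mup7, 0.186 for Mup9 and 0.14 for Obp2a without MttpLKO replicate 2, 0.13 for Gprc5a and 0.0595 for Pianp without control replicate 3, and 0.131 for Bmyc without control replicate 2. Some named genes not called with all libraries gained the call. Cidec did so without control replicate 1 (edgeR adjusted p = 0.00284), Acot3 and Acot4 without DKO replicate 1 (0.00251 and 0.0389) and Fabp2 without DKO replicate 2 (0.0282). Mgp gained it without MttpLKO replicate 1 (0.0466) and Meg3 without MttpLKO replicate 3 (0.0437).

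**Figure D2:**
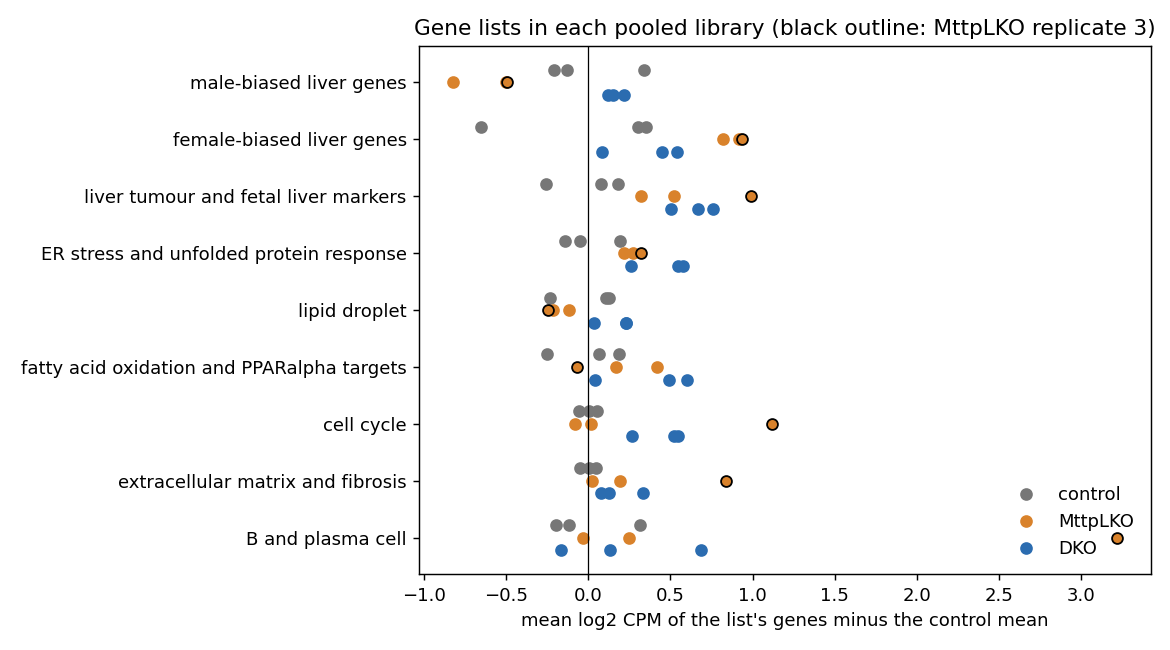
Each point is 1 library's mean log2 CPM over the genes of a list, minus the control mean, coloured by genotype, with MttpLKO replicate 3 outlined. The male-biased list lies between -0.827 and -0.496 in MttpLKO and between 0.117 and 0.215 in DKO, and the B and plasma cell list reaches 3.22 in MttpLKO replicate 3.

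DKO was compared with MttpLKO to see what germline Fabp1 loss adds. Of 25 lipid droplet genes 18 had higher values in DKO, with 2 called over all genes by edgeR, and 7 had lower values, with none called over all genes. Cidec went 4.58-fold up from 6.52 ± 1.28 to 29.9 ± 1.90 CPM (edgeR adjusted p = 0.00611), and Cidea, 14-fold up from 0.676 ± 0.313 to 9.46 ± 7.03 CPM (edgeR adjusted p = 0.0448). Both encode proteins that enlarge lipid droplets, and the list was called by camera (adjusted p = 0.000285; adjusted p = 0.328 with an estimated correlation). Apoa4 doubled its MttpLKO level, from 57.8 ± 6.28 to 116 ± 27.8 CPM (edgeR adjusted p = 0.0291), and Me1, the cytosolic malic enzyme gene that supplies NADPH for fatty acid synthesis, fell 1.7-fold (edgeR adjusted p = 0.0105). Of 27 male-biased liver genes 21 had higher values, with 5 called over all genes by edgeR, and 6 had lower values, with none called over all genes. Among those called were Mup11, Mup1 and Cyp4a12a, a fatty acid hydroxylase gene, at 3.79-fold, 3.33-fold and 1.83-fold (edgeR adjusted p = 0.00611, 0.0157 and 0.00845). The male-biased list was called by camera (adjusted p = 3.61e-14, and 0.214 with an estimated correlation). Hamp, the hepcidin gene, fell 2.22-fold from 2215 ± 659 to 998 ± 89.6 CPM (edgeR adjusted p = 0.0414).

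Among the named genes the largest change was in Mrap2, a melanocortin receptor accessory protein gene, with 2468 counts over the DKO libraries and 2 over the MttpLKO libraries, a ratio with a 95% counting interval of 388 to 11600 (edgeR adjusted p = 2.73e-05). Htra2, a mitochondrial serine protease gene, rose 21.8-fold from 10.0 ± 0.20 to 218 ± 44.2 CPM (edgeR adjusted p = 7.14e-08); it starts at 83051266 on chromosome 6, on the same chromosome as Fabp1. Mup9, Mup17, Mup18, Slc41a2 and Ces4a rose 14-fold, 7.39-fold, 6.36-fold, 5.5-fold and 5.45-fold. C1rb, C1s2, Pianp and Ces1b, which had risen in MttpLKO, fell 303-fold, 179-fold, 12.5-fold and 3.43-fold in DKO. Tpmt, the thiopurine methyltransferase gene, fell 2.47-fold (edgeR adjusted p = 0.000175), and Slco1a4 and Dsg1c fell 5.37-fold and 3.05-fold. Overall counts were 38 genes up and 21 down by edgeR's quasi-likelihood test, with 1342 at an unadjusted p under 0.05. Of the 59 called genes, 8 lay between 60066469 and 61801286 on chromosome 4, all Mup genes or a gene model among them, and 7 lay between 83925145 and 88599516 on chromosome 9, including Mrap2 and Me1.

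Lipid droplet genes were higher for 18 of 25, with 2 called over all genes and 4 higher and 1 lower when adjusted over the list alone. Their median log2 fold change of 0.16 was 0.045, 0.25 and 0.28 without DKO replicate 3, DKO replicate 1 and MttpLKO replicate 2. Cidea and Cidec are also adipocyte markers, and that list of 10 was higher too (camera adjusted p = 0.000994; adjusted p = 0.441 with an estimated correlation), with 2 called over all genes and 4 higher and 1 lower when adjusted over the list alone. VLDL and lipoprotein genes went both ways, with Apoa4 called and 4 higher and 4 lower when adjusted over the list alone, and Tm6sf2, needed for lipid loading of VLDL, 1.52-fold lower (edgeR adjusted p = 0.0794, but 0.0366 without MttpLKO replicate 3). That list was not called (camera adjusted p = 0.783), with a median of 0.04, a mean of -0.001 and a test pointing up. Fatty acid synthesis genes were lower for 18 of 25 with Me1 called by both adjustments, and Agpat2 was 1.43-fold higher (edgeR adjusted p = 0.287). Their camera adjusted p was 0.0497 (adjusted p = 0.726 with an estimated correlation). It was 0.426 and 0.121 without MttpLKO replicates 1 and 3, 0.178 and 0.348 without DKO replicates 2 and 3, and 0.0525 and 0.0552 without control replicates 1 and 2. PPARalpha and oxidation genes were higher for 31 of 38 with none called by edgeR with either adjustment, 7 at an unadjusted p under 0.05 and 3 called higher by DESeq2. Vnn1 and Ehhadh were 2.2-fold and 1.55-fold higher (edgeR adjusted p = 0.191 and 0.215). Their camera adjusted p of 0.000599 (adjusted p = 0.765 with an estimated correlation) was 0.253 without MttpLKO replicate 3 and 0.0733 and 0.073 without DKO replicates 2 and 3. Among 19 fatty acid uptake and binding genes Fabp1 alone was called, by both edgeR adjustments and DESeq2. Fabp7 was 2.43-fold higher (edgeR adjusted p = 0.486). The median of the 19 was 0.11 and the mean -0.13 in log2 units, and camera did not call the list (adjusted p = 0.418). The list holds Fabp1, deleted by design (log2 fold change -5.98), and 15 members were higher and 4 lower. Camera was not run without Fabp1, so this result does not settle how the other members moved as a group.

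Male-biased genes were higher in DKO for 21 of 27, with 5 called over all genes and 12 higher and 1 lower when adjusted over the list alone. Female-biased genes were lower for 13 of 19, with Slc22a26, an organic anion transporter family gene, among those called over all genes at 3.43-fold lower (edgeR adjusted p = 0.0442) and 5 lower when adjusted over the list alone (camera adjusted p = 0.000309; adjusted p = 0.441 with an estimated correlation). ER stress genes were higher for 21 of 30 with none called by edgeR over all genes, 6 higher when adjusted over the list alone, 10 at an unadjusted p under 0.05 and 4 higher by DESeq2 (camera adjusted p = 0.000599; adjusted p = 0.726 with an estimated correlation). Their median of 0.18 was 0.35 without MttpLKO replicate 3, and the list was called without each library in turn. Of 18 neutrophil markers listed 5 were tested, among them Lcn2, which is also on the acute phase and tumour marker lists. They were higher for 5 of 5, with none called over all genes by edgeR or DESeq2. By edgeR 2 were called when adjusted over the list alone and 2 had an unadjusted p under 0.05. The list's camera adjusted p was 0.000326 (adjusted p = 0.328 with an estimated correlation). Against control these 5 had a median log2 fold change of -1.42 in MttpLKO (4 lower, camera adjusted p = 0.122) and of 0.016 in DKO (3 higher, camera adjusted p = 0.0842). In MttpLKO edgeR called none over all genes and 1 higher and 2 lower when adjusted over the list alone, and DESeq2 called 1 higher. In DKO edgeR called Lcn2 higher by both adjustments, and DESeq2 called 1 higher. The list was called lower in MttpLKO without any 1 library but control replicate 1 or MttpLKO replicate 1 (camera adjusted p from 5.46e-06 to 0.0359). Without control replicate 1 that median was nearer 0 by over 1.5 times. In DKO the list was called higher without control replicate 1 (median 0.67, camera adjusted p = 0.000892). Acute phase genes were higher for 25 of 32, with Hamp called in the other direction, and 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000267; adjusted p = 0.726 with an estimated correlation); without DKO replicate 3 the camera adjusted p was 0.344. The mitochondrially encoded mRNA list was higher for 7 of 7 (camera adjusted p = 0.018; adjusted p = 0.726 with an estimated correlation) and also lost the call without DKO replicate 3 (camera adjusted p = 0.324). None of its genes was called by edgeR with either adjustment or by DESeq2, and 1 had an unadjusted p under 0.05. The mitochondrial share of counts was 7.20%, 5.84% and 7.96% in DKO replicates 1, 2 and 3, and 5.61% to 6.66% in the other libraries. Tumour and fetal markers did not differ as a group (20 of 43 higher, none called by edgeR with either adjustment, 7 at an unadjusted p under 0.05, 1 called lower by DESeq2, camera adjusted p = 0.783, median -0.012 with a test pointing up), with Meg3 1.76-fold lower and Mycn 2.17-fold higher (edgeR adjusted p = 0.197 and 0.222). Without MttpLKO replicate 3, in which this list was highest, it was called higher in DKO (camera adjusted p = 0.0166), as was the cell cycle list (camera adjusted p = 1.19e-05 against 0.989 with all libraries, where the median was -0.04 and the test pointed up). Mcm6 and Tk1, the cell cycle genes with the smallest p, were 1.74-fold and 1.28-fold lower (edgeR adjusted p = 0.472 and 0.594). Extracellular matrix genes were lower for 33 of 44 with none called by edgeR with either adjustment or by DESeq2 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0464; adjusted p = 0.831 with an estimated correlation), and this median turned from -0.22 to 0.026 without MttpLKO replicate 3. The matrix call was also lost without DKO replicate 2 or 3 (camera adjusted p = 0.12 and 0.324). In all, camera called 9 lists higher and 8 lower at the preset correlation and none with an estimated correlation. Among the 8 lower were xenobiotic P450 genes (26 of 35) and glucose handling genes (22 of 28). So were immediate early genes (17 of 22) and T and NK cell genes (16 of 18). In that order camera adjusted p was 0.00172, 0.0198, 0.015 and 0.0321 (0.726, 0.328, 0.726 and 0.831 with an estimated correlation). EdgeR called none of their members over all genes. Xenobiotic scores were -0.269 to 0.177 in DKO and -0.094 to 0.375 in MttpLKO. Mgp and Col12a1 of the matrix list were 2.35-fold lower and 1.41-fold higher (edgeR adjusted p = 0.295 and 0.445).

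The count of 59 called genes was 22 without MttpLKO replicate 2, 37 without DKO replicate 2, 34 in the 6 compared libraries alone, 206 with DESeq2 on all genes with a count and 214 with DESeq2 on the genes edgeR tested. Of the 25 named genes called, 12 (Fabp1, Mrap2, Htra2, Mup9, Slc41a2, C1rb, C1s2, Pianp, Ces1b, Tpmt, Mup11 and Cidec) were called under each alternative. Without MttpLKO replicate 2 the call was lost by Cidea (edgeR adjusted p = 0.273), Apoa4 (0.142), Me1 (0.054), Hamp (0.215), Mup17 (0.0637), Mup18 (0.0631), Mup1 (0.0745), Cyp4a12a (0.0579), Ces4a (0.0862), Slco1a4 (0.102), Dsg1c (0.0991) and Slc22a26 (0.138), among others. Without DKO replicate 2 it was lost by Cidea (0.134), Ces4a (0.0655), Slco1a4 (0.0892), Hamp (0.155), Mup1 (0.0644), Slc22a26 (0.146), Apoa4 (0.0914) and Me1 (0.0585), among others. Without DKO replicate 3 or control replicate 3 Apoa4 stood at 0.103 and 0.0566. Slc22a26, with 34 counts in DKO and 133 in MttpLKO, lost the call without each library in turn (0.0538 to 0.153). Hamp lost it without any library but MttpLKO replicate 1, and Cidea without any but control replicate 1 or DKO replicate 3.

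**Figure D3:**
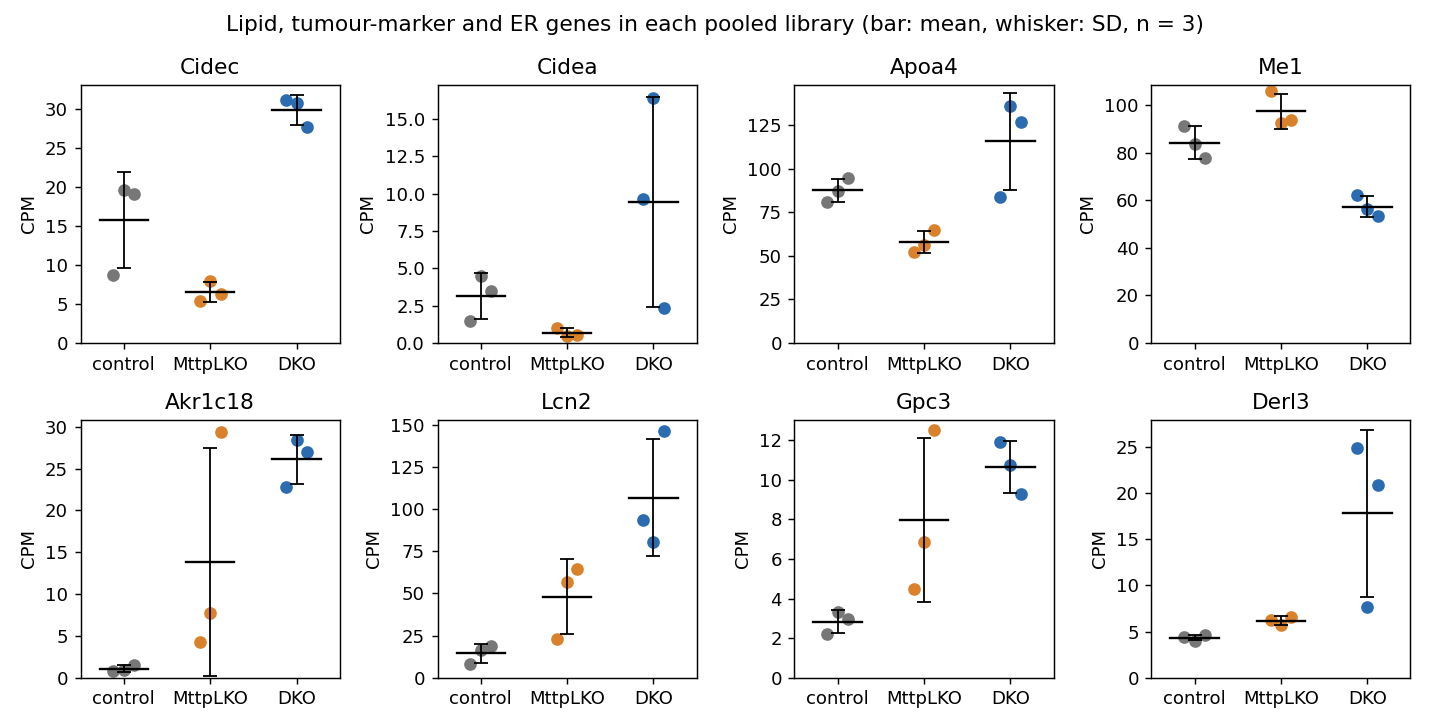
CPM of 8 named genes in each library, with 1 point per pool, a line at the mean and whiskers of 1 SD (n = 3). Cidec averages 15.8, 6.52 and 29.9 CPM in control, MttpLKO and DKO, and Akr1c18 averages 1.09, 13.8 and 26.1 CPM.

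DKO was then compared with control. The liver of DKO mice held more Lcn2, Akr1c18 and Gpc3, all on the fixed tumour and fetal liver marker list, and more Derl3 and Dnajb11, which encode endoplasmic reticulum quality control proteins. Lcn2, the lipocalin-2 gene, rose 7.43-fold from 14.4 ± 5.52 to 107 ± 34.7 CPM (edgeR adjusted p = 0.0137). Akr1c18 rose 23.7-fold to 26.1 ± 2.92 CPM, and Gpc3, the glypican-3 gene, rose 3.77-fold from 2.82 ± 0.58 to 10.7 ± 1.32 CPM (edgeR adjusted p = 0.0153 and 0.0423). Derl3 rose 4.09-fold and Dnajb11 1.61-fold (edgeR adjusted p = 0.0375 and 0.0499). Cpe, the carboxypeptidase E gene, rose 8.69-fold, Col4a3, a basement membrane collagen gene, 4.5-fold, and Nt5e, the gene of the ectonucleotidase CD73, 4.42-fold (edgeR adjusted p = 0.00165, 0.00464 and 0.00258).

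Mrap2, Gh and Htra2 were also higher than in control, by 371-fold, 219-fold and 21-fold. The falls were Rpl34 at 12-fold, Hamp2 at 5.17-fold, Slco1a4, an organic anion transporter gene, at 5.05-fold, Crygn at 2.3-fold, Fkbp14 at 2.1-fold, Mup20 at 1.72-fold and Slc20a1 at 1.66-fold, with edgeR adjusted p from 2.13e-06 to 0.0446 over these 7. Named genes included, 35 rose and 14 fell by edgeR's quasi-likelihood test, and 1656 genes had an unadjusted p under 0.05. The run of calls on chromosome 9 appeared here too, with 6 between 83925145 and 88599516, Mrap2 and Nt5e among them.

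ER stress genes were higher for 24 of 30, with 2 called over all genes and 14 when adjusted over the list alone (camera adjusted p = 7.98e-13; adjusted p = 0.519 with an estimated correlation). Hspa5, the gene of the chaperone BiP, named after its values were seen, had a log2 fold change of 0.80 (edgeR adjusted p = 0.138). Tumour and fetal markers were higher for 34 of 43, with 3 called over all genes and 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 6.27e-09; adjusted p = 0.519 with an estimated correlation). PPARalpha and oxidation genes were higher for 34 of 38, with none called by edgeR over all genes, 5 when adjusted over the list alone, 16 at an unadjusted p under 0.05 and 4 by DESeq2 (camera adjusted p = 1.28e-08; adjusted p = 0.827 with an estimated correlation), Ehhadh and Acot3 being 1.72-fold and 2.28-fold higher (edgeR adjusted p = 0.103 and 0.209). Acute phase genes were higher for 27 of 32, with Lcn2 called over all genes and 6 when adjusted over the list alone (camera adjusted p = 4.49e-09; adjusted p = 0.822 with an estimated correlation), and a median of 0.46 that was 0.11 without DKO replicate 3. Fatty acid and triglyceride synthesis genes were lower for 21 of 25, with none called by edgeR over all genes, 1 when adjusted over the list alone, 7 at an unadjusted p under 0.05 and 2 by DESeq2 (camera adjusted p = 5.52e-05; adjusted p = 0.792 with an estimated correlation), Me1 and Scd1 being 1.47-fold and 2.22-fold lower (edgeR adjusted p = 0.0667 and 0.216). Cell cycle genes were higher for 34 of 41 with none called by edgeR with either adjustment or by DESeq2 and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.000548; adjusted p = 0.827 with an estimated correlation), with Cdkn3 and E2f8 at 3.78-fold and 2.02-fold (edgeR adjusted p = 0.29 and 0.362). These 6 lists stayed past the preset-correlation threshold without each library in turn. In all, camera called 7 lists higher and 2 lower at the preset correlation and none with an estimated correlation; 14 lists were called without control replicate 3.

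Lipid droplet genes were not called as a list against control (camera adjusted p = 0.123, but 0.0357, 0.0384 and 0.00822 without control replicate 2, control replicate 3 and DKO replicate 1), and Cidec and Cidea were 1.89-fold and 2.98-fold higher (edgeR adjusted p = 0.214 and 0.353). Of the VLDL and the fatty acid uptake lists only the deleted genes Mttp and Fabp1 were called, by both edgeR adjustments and DESeq2. Apoa5 and Slc27a4 were 1.34-fold lower and 1.23-fold higher (edgeR adjusted p = 0.342 and 0.344). Camera called neither list (adjusted p = 0.275 and 0.26), and the uptake list had a median of 0.12, a mean of -0.23 and a test pointing down. Each list holds a deleted gene, and camera was not run without it, so these results do not settle how the other members moved. Extracellular matrix genes were higher for 37 of 44 with none called by edgeR with either adjustment, 4 at an unadjusted p under 0.05 and 1 called lower by DESeq2 (camera adjusted p = 0.0322; adjusted p = 0.827 with an estimated correlation; 0.263, 0.11 and 0.0624 by camera without DKO replicate 1, DKO replicate 2 and control replicate 2). Col5a3 of this list was 1.81-fold lower and Mmp12 2.72-fold higher (edgeR adjusted p = 0.209 and 0.399). Male-biased and female-biased lists were not called (camera adjusted p = 0.463 and 0.0874), although Mup20 fell. The male-biased list was called higher without control replicate 1 (camera adjusted p = 0.00451), and the female-biased list was called higher without control replicate 2 or 3, MttpLKO replicate 3 or DKO replicate 1 (camera adjusted p = 0.00318, 0.00191, 0.0449 and 0.000976). Of the hepatocyte identity genes edgeR called none with either adjustment, 3 had an unadjusted p under 0.05 and DESeq2 called 1 lower. That list had a median log2 fold change of 0.04 with a test pointing down (camera adjusted p = 0.862).

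The count of 49 called genes was 23, 15 and 15 without control replicates 1, 2 and 3, 28 and 20 without DKO replicates 1 and 3, 100 without MttpLKO replicate 3, 256 with DESeq2 on all genes with a count and 255 with DESeq2 on the genes edgeR tested. Of the 20 named genes called, 9 (Mttp, Fabp1, Mrap2, Gh, Htra2, Cpe, Col4a3, Nt5e and Rpl34) were called under each alternative. Lcn2, Akr1c18, Gpc3, Derl3 and Dnajb11 lost the call without control replicate 2 (edgeR adjusted p = 0.0737, 0.109, 0.153, 0.201 and 0.287), control replicate 1 (0.0536, 0.0821, 0.128, 0.112 and 0.0667), control replicate 3 (0.0587, 0.0715, 0.196, 0.171 and 0.255) and DKO replicate 3 (0.0532, 0.0532, 0.0906, 0.106 and 0.134). Gpc3, Derl3 and Dnajb11 also lost it without DKO replicate 1 (0.137, 0.127 and 0.16) and MttpLKO replicate 2 (0.0559, 0.0509 and 0.0719). The falls of Hamp2, Slco1a4, Crygn, Fkbp14, Mup20 and Slc20a1 were at edgeR adjusted p from 0.058 to 0.225 without control replicate 2.

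Both deletion genotypes shared 12 changes against control. The 9 shared rises were Gh, Akr1c18, Slc16a5, Lrp6, Abhd2, Igdcc4, Erich4, Hoxc8 and Gm23616, and the 3 shared falls were Mttp, Rpl34 and Crygn; those outside the naming rule are listed because both counts are small. Independent lists of these sizes would share 0.0784 rises and 0.0171 falls, a figure that leaves out the use of the same controls. Mttp, deleted by design in both genotypes, was bound to be among the shared falls. Simulated unchanged genotypes with the same controls shared 0 genes. They made at most 3 and 1 calls against control, too few to weigh sharing among 51 and 49. Over all genes the covariance of log2 fold changes was 0.0966 against a mean of 0.038 (highest 0.0406) in 40 simulations of unchanged genotypes, but their correlation was 0.509 against 0.498 (highest 0.52), within the simulated values. Simulations with DKO set equal to MttpLKO shared 43 to 50 genes. These kept the observed changes of the called genes and made 45 to 55 calls in MttpLKO vs control. Changes picked for passing the test tend to be overstated, so that mark may be too high for weighing the 12. With 3 controls there can be no 2 separate control groups of at least 2 libraries, so part of the excess may come from the shared controls. Leaving out each control replicate gave 6, 4 and 3 shared genes, leaving out MttpLKO replicate 2 gave 7, leaving out DKO replicate 1 or 3 gave 6, and DESeq2 gave 56 on all genes with a count and 54 on the genes edgeR tested.

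Of the 51 genes called in MttpLKO vs control, none moved further in the same direction in DKO and 15 moved back, by edgeR's quasi-likelihood test in both comparisons. Both comparisons use the same MttpLKO libraries with opposite sign, so the spread of those libraries alone makes opposite changes. C1rb, C1s2, Pianp, Gm13394, Ces1b, Tpmt, Enho and Pik3c2g rose in MttpLKO and fell in DKO, and Mug2, Mup9, Mup7, Crygn, Adipor2, Gadd45gip1 and Wdr83os fell and then rose. Crygn alone of these also differed from control in DKO. In 40 simulations with DKO set equal to MttpLKO at most 1 gene moved back. They made at most 2 calls in DKO vs MttpLKO against 59 here, so any real difference would exceed them. They do not show a reversal of the MttpLKO changes in particular. Of the 51 genes, 44 (86.3%) had opposite signs in the 2 comparisons, against 42% to 65.3% of calls in these simulations. Over all genes the correlation of log2 fold changes was -0.486 and the covariance -0.0908. Simulated unchanged genotypes gave means of -0.494 and -0.0376. Adipor2, Mug2, C1rb, C1s2, Pianp and Pik3c2g lay on the chromosome 6 stretch where calls were dense, and Gadd45gip1 and Wdr83os on that of chromosome 8. Without control replicate 2 or 3 the count was 9, without MttpLKO replicate 2 it was 7, without DKO replicate 2 it was 9, and with DESeq2 56 moved back (55 on the genes edgeR tested) and 2 moved further. Without MttpLKO replicate 3, 1 gene moved further.

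In the joint test of the 3 genotypes, 100 genes differed by edgeR's quasi-likelihood test, and 1518 had an unadjusted p under 0.05. The first 2 principal components carried 22.3% and 20.8% of the variance. The second ordered the genotypes, with control at 19.7 to 23.8, MttpLKO at 1.61 to 2.95 and DKO at -42.0 to -7.13. The count was 64, 47 and 47 without control replicates 1, 2 and 3 and 56 without MttpLKO replicate 2, and 394 with the DESeq2 likelihood ratio test on all genes with a count, or 406 on the genes edgeR tested.

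**Figure D4:**
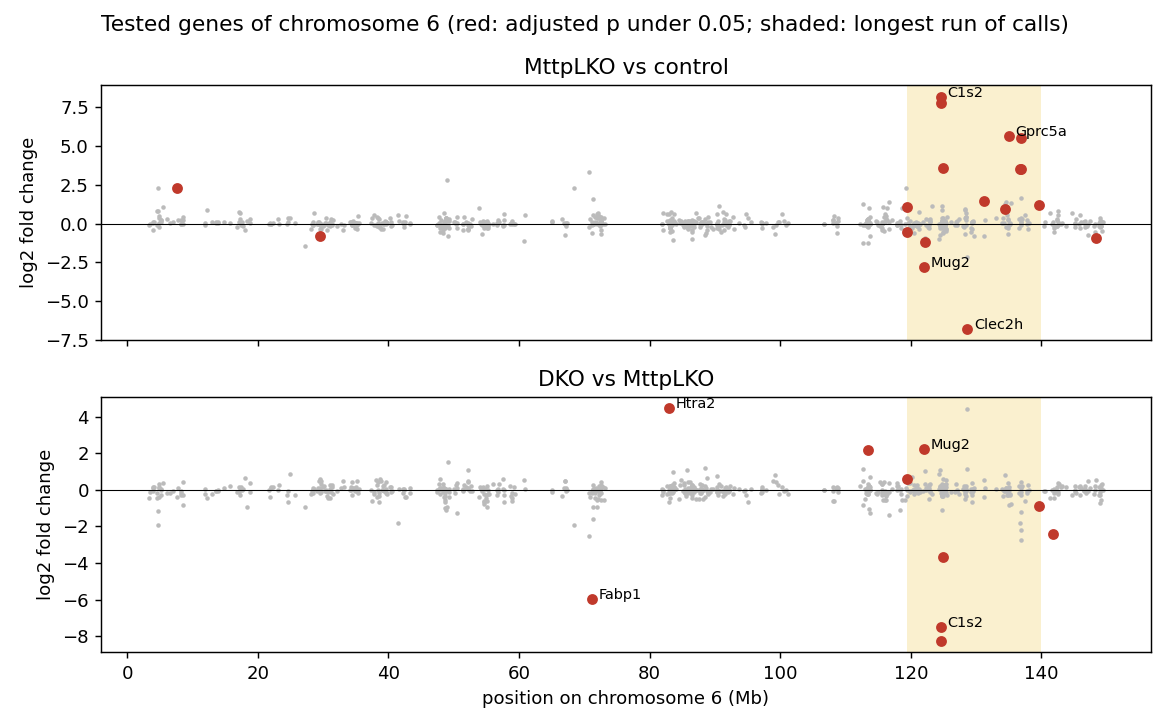
Log2 fold change of each tested gene along chromosome 6 in Mb, for MttpLKO vs control above and DKO vs MttpLKO below, with called genes in red and the stretch from 119353150 to 139969284 shaded. The shaded stretch holds 15 of the 51 calls of the first comparison, and Fabp1 and Htra2 are called in the second.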

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

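The robust fit, the library weights and DESeq2 on filtered genes were chosen after seeing the data; the other alternatives below were planned. Mttp and Fabp1 kept their direction and side of the threshold in the 3 comparisons under every alternative run. The called genes in MttpLKO vs control, DKO vs MttpLKO and DKO vs control (51, 59 and 49) and among the 3 genotypes (100) numbered 171, 180, 201 and 337 without the low-count filter, 166, 206, 256 and 394 with DESeq2 on the 25483 genes with a count, 165, 214, 255 and 406 with DESeq2 on the 14741 filtered genes, and 201, 128, 305 and 506 with limma-voom and library weights. With the 6 compared libraries alone the DKO vs MttpLKO count was 34 and the DKO vs control count 78. DESeq2 gave 56 shared genes, 56 that moved back and 2 that moved further (54, 55 and 2 on the filtered genes), against 12, 15 and 0. Leaving out each library gave 14 to 54, 22 to 73, 15 to 100 and 47 to 136 called genes, 3 to 17 shared genes, 7 to 18 that moved back and 0 to 1 that moved further; fewer samples are part of each such setting, and other causes were not tested. The counts with other scaling, the stricter filter, unweighted limma-voom, the robust fit and the 20 most abundant genes removed lay within 1.5 times the main counts. With the replicate number as a block, as if equal numbers paired the libraries, 35, 43 and 40 genes were called in the 3 comparisons. The gene lists called by camera (22, 17 and 9) numbered 0, 0 and 0 with an estimated correlation and with fry's directional test, and 6, 16 and 14 with fry's mixed test; they ranged from 17 to 24, 13 to 20 and 9 to 14 without each library. Of 1575 list results under alternatives 1345 kept direction and side, 66 gained and 158 lost the threshold and 6 reversed; of 2113 named gene results these were 1795, 69, 249 and 0. All 6 reversals of a list test's direction came without MttpLKO replicate 3. In MttpLKO vs control the cell cycle median was then -0.004 (highest 0.688 over the libraries left out) and the T and NK cell median -0.448 (highest 0.929). In DKO vs MttpLKO the matrix median was 0.026 (lowest -0.394), recruited macrophage 0.253 (lowest -0.307), T and NK cell 0.161 (lowest -1.18) and B and plasma cell 0.152 (lowest -1.868). Apart from that library's own scores, which lay apart from the other MttpLKO pools, the cause was not tested. With the filter kept DESeq2 still called more genes than edgeR, so the wider gene set is not needed for its higher counts. On simulated counts DESeq2 made 23, 34 and 40 false calls in the 3 comparisons and edgeR 6, 10 and 7. Those counts were drawn at edgeR's own dispersions, which may favour edgeR. What part of the added calls here is false was not tested, and the cause was not tested for the other counts. Depth limits genes near the floor: at 23268389 to 27918197 counts a library, Cdkn3 rested on 10 counts over the control libraries.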

Other observations

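The tests of other splits, of gene positions, of growth hormone counts and of the male-biased list were written after the results they concern were seen. The planned lists of immune cells are given first. Resident macrophage (Kupffer cell) genes were lower in MttpLKO than in control for 13 of 19 (camera adjusted p = 0.00544; adjusted p = 0.525 with an estimated correlation) and higher in DKO than in MttpLKO for 15 of 19 (camera adjusted p = 0.000503; adjusted p = 0.726 with an estimated correlation), with none called by edgeR over all genes in either, 0 and 1 when adjusted over the list alone, 6 and 6 at an unadjusted p under 0.05, and 0 and 1 called higher by DESeq2. Their score was -0.945 and -0.628 in MttpLKO replicates 1 and 2 and 0.329 in replicate 3. The first call was lost without MttpLKO replicate 1 or 2 (camera adjusted p = 0.36 and 0.0582), the second without MttpLKO replicate 1 or DKO replicate 2 (0.149 and 0.097). Sinusoidal endothelial genes (18 of 22) and red blood cell genes (8 of 9) were lower in MttpLKO than in control too (camera adjusted p = 0.00285 and 0.00892; adjusted p = 0.525 and 0.501 with an estimated correlation). By edgeR none was called over all genes in either list, 1 and 0 were lower when adjusted over the list alone and 1 and 1 had an unadjusted p under 0.05; DESeq2 called 1 lower and 0. The sinusoidal score was -0.441, -0.156 and 0.07 in MttpLKO replicates 1, 2 and 3, and that call was lost without control replicate 1 or MttpLKO replicate 1 (camera adjusted p = 0.109 and 0.374). The red blood cell call was lost without control replicate 2 or MttpLKO replicate 1 (camera adjusted p = 0.239 and 0.127). Marco, a macrophage scavenger receptor gene chosen after its values were seen, stood at 4.46, 2.13 and 5.81 CPM in control, MttpLKO and DKO, with no difference past the edgeR test.

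Recruited macrophage genes were higher in DKO than in control for 21 of 26 with none called by edgeR with either adjustment, 7 at an unadjusted p under 0.05 and 1 called higher by DESeq2 (camera adjusted p = 0.00611; adjusted p = 0.827 with an estimated correlation), a call lost without DKO replicate 1 or 2 (0.126 and 0.11). Interferon response genes were lower in DKO than in control for 32 of 38, with none called by edgeR with either adjustment or by DESeq2 on all genes with a count, 1 lower by DESeq2 on the genes edgeR tested and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.00299; adjusted p = 0.827 with an estimated correlation; 0.191 by camera without DKO replicate 3). B and plasma cell genes were lower in DKO than in MttpLKO for 16 of 16 with none called by edgeR with either adjustment or by DESeq2 and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000912; adjusted p = 0.726 with an estimated correlation), and the median was 0.152 without MttpLKO replicate 3 (camera adjusted p = 0.56).

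In other splits of the 6 libraries of a comparison into 3 and 3, with the remaining genotype kept, the highest gene count was 1 for MttpLKO vs control, 7 for DKO vs MttpLKO and 0 for DKO vs control, against 51, 59 and 49 for the real split, which was 1 of 10 splits with as many in each case. For the number of lists called by camera the real values were 22, 17 and 9 and the highest others 20, 20 and 16, and 1, 3 and 8 of 10 splits gave as many. The splits of 6 libraries are too few for a share under 0.05. Among 100 drawn splits of the 9 libraries into 3 groups of 3, 1 gave as many genes as the real 100, the real one itself, and the highest other gave 20. This argues against chance for the joint test but cannot exclude it, since the number of drawn splits bounds how small a share can be seen.

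Called genes lay close together on chromosomes. Pairs of overlapping genes, or of genes whose symbols start with the same letters, were left out. Gene models with Gm or Rik names, and symbols with few letters before the first digit, each counted as their own family. Related neighbours such as C1rb and C1s2, or Mup genes and a gene model among them, could thus still pair. On this count 57, 38 and 16 pairs of calls lay within 5 Mb in MttpLKO vs control, DKO vs MttpLKO and DKO vs control. The means in 10000 random placements were 7.36, 9.86 and 6.79 (permutation test of call positions, p = 1e-04, the smallest these can give, for the first and second, and 0.008 for the last). This argues against chance placement, though related neighbours may add to the excess. On the longest stretch, from 119353150 to 139969284 on chromosome 6, the median log2 fold change of 156 tested genes was 0.034 (95% interval -0.032 to 0.093), with 11 calls up and 4 down, which argues against a change in copy number there; its uncalled genes had an unadjusted p under 0.05 in 17.7% against 6.5% elsewhere (Fisher p = 5.85e-06), as did those of the chromosome 8 stretch in 16.9% against 6.6% (Fisher p = 0.00515), while no excess passed on chromosome 9 in DKO vs MttpLKO (7.7% against 8.7%, p = 0.696) and DKO vs control (21.4% against 10.9%, p = 0.192) or on chromosome 6 in DKO vs MttpLKO (12.3% against 8.7%, p = 0.205). On the chromosome 4 stretch of Mup genes in DKO vs MttpLKO the median of 18 tested genes was 1.51 (95% interval 1.17 to 1.80) with 8 calls up and 0 down, and 80% of its uncalled genes had an unadjusted p under 0.05 against 8.7% elsewhere, so copy number and reads shared among Mup genes stay open there. A candidate explanation left open is DNA of another mouse strain kept around a targeted or transgene site: in DKO vs MttpLKO, genes within 15 Mb of Fabp1 had an unadjusted p under 0.05 in 8.8% against 9.1% elsewhere (odds ratio 0.96, 95% interval 0.47 to 1.79, Fisher p = 1), which bears on genes near Fabp1 alone and leaves strain DNA undecided both there and on the stretches above, and no sequence was used here. Htra2, called in DKO vs MttpLKO, lies within the window around Fabp1. No window was tested around Mttp, on whose chromosome Rpl34 lies. The genotype's own effect on the called genes of these stretches also stays open, untested.

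Growth hormone (Gh) reads numbered 2046 in the 6 MttpLKO and DKO libraries and 5 in the 3 controls. Of other pituitary hormone genes Prl, Cga, Tshb, Lhb and Fshb summed to 0 counts in those 6 libraries and Pomc to 26, against 16 in the 3 controls, which argues against pituitary tissue in the pools. A candidate explanation is growth hormone sequence carried by the Cre transgene, as some such constructs have: 6 of 6 libraries with the deletion exceeded every control (5.27 to 17.7 CPM on raw totals against at most 0.12), but gene totals do not separate transgene from endogenous Gh and the labels name no Cre driver. It cannot be told apart from an effect of Mttp loss on the liver's own Gh, which was not tested.

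Male-biased liver genes were lower in MttpLKO than in control and in DKO. Without the 6 Mup genes the 21 others still passed camera in both comparisons (adjusted p = 1.61e-06 and 1.15e-08; adjusted p = 0.501 and 0.328 with an estimated correlation), which argues against reads shared among Mup genes as the whole cause. Mean log2 fold change of 4 Y-linked genes in MttpLKO vs control was 0.008 (95% interval -0.146 to 0.163). This interval takes the 4 genes as independent though they come from the same pools, so it may be too narrow. Xist, chosen after its values were seen, read at most 0.702 CPM in any library. Together these values argue against female mice in the pools. Without 1 MttpLKO library at a time the largest camera adjusted p at the preset correlation was 3.76e-10. The list score was -0.501, -0.827 and -0.496 in the MttpLKO pools against -0.208 to 0.336 in control. This argues against a single MttpLKO pool as the source, while spread between pools in general was not excluded. Left open is a genotype effect on sex-biased expression, for which no direct test was run. The preset correlation may overstate it, since camera with the estimated correlation gave adjusted p = 0.19 and 0.214 for the full list.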
